A study of Mus musculus with 4 samples.

How the data were processed

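The deposited files are, per the file headers, Space Ranger 2.0.0 matrices of raw counts: UMIs per gene and spot for 32285 genes, with the grid position of each spot and the image scale factors. Per the labels, fresh frozen tissue was sectioned at 8 µm, libraries were made with 10x Genomics Visium slides, and the authors processed the reads with Space Ranger against mm10. The counts were checked on the files: all values are whole numbers, no normalization had been applied, and the matrices hold spots over tissue alone. The tissue images were not used here, and the cDNA chemistry version is not given in the sources used here. Groups and replicate numbers follow the sample titles: E13.5 (1 section), E16.5 (1 section) and P0 (2 sections). The animals behind a section are not named in the labels.

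Spots with at least 500 UMIs were kept, and no gene was removed. Totals ranged from 7357333 UMIs (P0 replicate 2) to 105835664 UMIs (E16.5). Mitochondrial genes held 2.52%, 4.34%, 5.42% and 5.72% of UMIs at E13.5, E16.5 and in the P0 replicates, and the blood list 3.05%, 5.06%, 0.0866% and 0.0777%. Levels are UMIs per 1000000 UMIs (CPM) with exact Poisson 95% intervals, and shares of spots carry exact Clopper-Pearson 95% intervals; both cover counting error only. Genome positions are those of the GRCm38.p6 RefSeq table, joined by symbol, which matched 26259 of the 32285 genes and 44 of 44 genes named by rule.

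Spots were scored as the mean over marker genes of log(1 + UMIs per 10000). Epithelial markers were 10 genes (Epcam, Cdh1, Krt5, Krt14, Krt15, Krt8, Krt18, Krt19, Perp, Dsp), smooth muscle markers 6 (Myh11, Acta2, Tagln, Cnn1, Actg2, Lmod1) and striated muscle markers 8 (Acta1, Actc1, Myh3, Myh8, Tnnt3, Tnni1, Mylpf, Ttn). Epithelium-rich and muscle-rich spots were the highest 25% of a P0 section or 2% of an embryo section; 0 spots fell in both. These are mixtures: in the P0 sections 159 and 121 spots scored within 10% of the epithelial limit. The marker genes were left out of the tests and counts between P0 regions, and the selecting markers out of the list medians between stages. In the embryo sections the marker sets were themselves placed among random lists for Lgr5-UMI spots.

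For P0, counts were summed per section and region (6 sums, epithelium-rich, muscle-rich and other) and fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM, filterByExpr with the region as group), with the section as a block and Benjamini-Hochberg adjustment at 0.05. Spots with at least 1 Lgr5 UMI and all other spots gave 4 sums, fitted in the same way with Lgr5 left out and 1 residual degree of freedom. With the section as a block, the p-values measure how far the difference within a section varies between 2 sections, not between a known number of animals. The variance of a gene rests mostly on that of other genes. These count for 17.1 degrees of freedom beside 2 residual ones between regions, and for 9.33 beside 1 in the Lgr5-UMI fit. Gene lists were tested with camera of limma 3.58.1 on voom log2 CPM at a preset correlation of 0.01 and with an estimated correlation. Beside it fry tests whether a list's genes move, on balance, to a side, without comparing them with other genes. Members were counted with p adjusted over all genes and over the list alone. A simulation with known changes at the dispersion of each fit recovered 63.9% of genes changed by 1 log2 and 96.9% of those changed by 2 log2 between regions, with 5 unchanged genes called of 12474. For the Lgr5-UMI fit it recovered 63.6% and 98.0%, with 3 unchanged genes called of 12579. Simulated levels and changes were the same in both sections, so these rates do not cover effects that differ between sections.

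Comparisons with E13.5 or E16.5 have no replicate and were described by log2 ratios of CPM (pseudocount 0.5; P0 as the mean of the log2 values of its sections, and for Lgr5 as pooled UMIs with an exact conditional interval). The median log2 ratio of each list was placed among 10000 random lists of the same size matched on expression in 20 bins, using genes with at least 20 UMIs. On simulated data 2 of 60 unchanged lists fell outside the central 95% of random lists, and 19 of 20 lists raised by 1.5 were found. The simulated genes were independent, so these rates do not hold for lists of genes that vary together. Where a gene had 0 UMIs in a sum, medians were also computed with it at 3 counts. The median over all genes of the ratios was −0.19 from E13.5 to E16.5 in rule spots (−0.08 with TMM factors) and −0.25 in their neighbours (−0.06).

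The lists, the region rules and the tests were fixed before the data were examined. The 27 lists tested were Wnt receptors and feedback, Wnt ligands and modulators, Hedgehog, BMP, FGF and Notch pathways, basal, suprabasal, and ciliated and columnar epithelium, smooth muscle, striated muscle, muscle progenitors, fibroblast and matrix, endothelium, enteric neurons and glia, interstitial cells, immune cells, blood, mesothelium, cartilage, stomach, thymus and thyroid, liver, central nervous system, heart, proliferation and stress response. Isl1, Myf5 and Fabp7 stand in more than 1 list. Genes named in the text are Lgr5 and list members, and by size: for the P0 regions the 12 largest changes in each direction past 0.05 with the same sign in both sections and at least 50 CPM, for Lgr5-UMI spots the 10 largest of the same kind whether or not they passed, and for stages the 10 largest ratios with at least 50 UMIs. Genes named Gm or Rik and mitochondrial, ribosomal and hemoglobin genes were passed over.

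Alternatives planned in advance were DESeq2 size factors and the DESeq2 1.42.0 Wald test, no filter, no replicate block, each P0 section left out, removal of mitochondrial, ribosomal and hemoglobin genes, a minimum of 2000 UMIs or none, each spot thinned to 2000 UMIs, other shares of spots (15% and 35%, or 1% and 5% in embryo sections), smooth or striated markers alone, other spots matched on total UMIs, at least 2 Lgr5 UMIs, groups of at least 3 adjacent spots, and TMM factors. Chosen after seeing the data were thinning to 10000 UMIs, matching on total UMIs and region, leaving out detached spots, the tissue piece as the block, the split of epithelium-rich spots by marker, and the Actg2 strip. Sums and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and fits with R 4.3.3. Random draws had fixed seeds.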

Results

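Spatial transcriptomes were collected from 4 sections of wild-type mouse tissue, each 8 µm thick, on Visium slides, whose barcoded spots capture the RNA of the cells lying above them. A section labelled as mouse embryo was measured at the embryonic stage E13.5 and another at E16.5, and 2 sections labelled as esophagus were measured at postnatal day 0 (P0). The files held 3228 spots over tissue and 98645152 unique molecular identifiers (UMIs, counts of captured molecules) at E13.5, 3593 spots and 105835664 UMIs at E16.5, 366 spots and 10261248 UMIs in P0 replicate 1, and 271 spots and 7357333 UMIs in P0 replicate 2. Spots with at least 500 UMIs were kept, which left 3220, 3588, 363 and 264 spots with medians of 29289, 26701.5, 25465 and 25619 UMIs. E13.5 and E16.5 have 1 section each, so values that involve them carry counting intervals (95%) and no test. Levels are UMIs per 1000000 UMIs (CPM) summed over spots, and every spot holds a mixture of cells.

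Lgr5 (ENSMUSG00000020140, GRCm38.p6 chromosome 10, 115450314 to 115587780) encodes a receptor for R-spondins that raises Wnt signalling and marks progenitor cells in several epithelia. The series asks how Lgr5-marked progenitors contribute to the epithelium and muscle of the developing esophagus, and the level of the transcript in each section is the starting point. Lgr5 was detected in all 4 sections at a low level. It stood at 5.24 CPM at E13.5 (4.80 to 5.71) and 3.73 CPM at E16.5 (3.37 to 4.12). The P0 sections held 6.63 CPM (5.15 to 8.40) and 8.02 CPM (6.11 to 10.3), a mean of 7.32 ± 0.985 CPM (SD, n = 2). Spots with at least 1 Lgr5 UMI made up 11.5% of spots at E13.5 (370 of 3220, exact binomial interval 10.4 to 12.6) and 9.42% at E16.5 (338 of 3588, 8.48 to 10.4). At P0 they made up 16% (58 of 363, 12.4 to 20.2) and 16.7% (44 of 264, 12.4 to 21.7), a mean of 16.3 ± 0.487% (SD, n = 2). The embryo values average over all tissues of the section and the P0 values over esophagus, so stage and dissection change together.

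Where Lgr5 lay within each section was compared between epithelium-rich and muscle-rich spots, the highest 25% of P0 spots or 2% of embryo spots by epithelial or muscle marker genes. Lgr5 was highest in epithelium-rich spots of the E13.5 section, at 41.3 CPM (31.7 to 53.0, 62 UMIs in 64 spots), against 9.49 CPM in muscle-rich spots (5.62 to 15) and 4.59 CPM in all other spots (4.17 to 5.04). At E16.5 the epithelium-rich spots held 14.3 CPM (9.14 to 21.2, 24 UMIs in 72 spots), the muscle-rich spots 1.21 CPM (0.250 to 3.55, 3 UMIs) and the rest 3.62 CPM (3.26 to 4.01). In the P0 sections the epithelium-rich spots held 7.82 CPM (5.24 to 11.2) and 8.34 CPM (5.34 to 12.4), the muscle-rich spots 6.06 CPM (3.13 to 10.6) and 3.19 CPM (1.04 to 7.45), and the rest 5.90 CPM (3.89 to 8.59) and 10.3 CPM (6.95 to 14.7). A Lgr5 UMI was present in 39.1% of epithelium-rich spots at E13.5 and 27.8% at E16.5, and in 24.2% and 25.8% of those at P0, against 13.2% and 7.58% of muscle-rich P0 spots. The P0 epithelium-rich spots were deeper, with medians of 39325 and 38936.5 UMIs against 20274 and 22535.5 in muscle-rich spots. With each spot thinned to 10000 UMIs, chosen after the data were seen, the P0 shares were 12.1% and 4.55% in epithelium-rich, 4.60% and 3.23% in muscle-rich and 5.20% and 9.24% in other spots, from 2 to 11 spots each.

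In the P0 fit between these regions Lgr5 had a log2 fold change of 1.0 ± 0.42 (SE, 2 sections) towards the epithelium and an adjusted p of 0.0513, which does not pass 0.05. It passed with smooth muscle markers alone (1.46, adjusted p = 0.0117), with no filter on low counts (0.0258), with at least 2000 UMIs per spot (0.0363), without detached spots (0.0404, a setting chosen after the data were seen) and with DESeq2 size factors (0.0437), and had an adjusted p of 0.620 with striated markers alone. Without P0 replicate 1 its log2 ratio was 1.28, and without P0 replicate 2 it was 0.33. The muscle value depends on the kind of muscle, in the embryo sections and at P0. With smooth muscle markers alone the muscle-rich spots held 0.473 CPM at E13.5 (1 UMI) and 9.31 CPM at E16.5. With striated markers alone the muscle-rich spots of P0 replicate 1 held 8.65 CPM (16 UMIs) against 8.28 CPM in its epithelium-rich spots. Those of P0 replicate 2 held 7.87 CPM (11 UMIs) against 8.96 CPM.

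**Figure D1:**
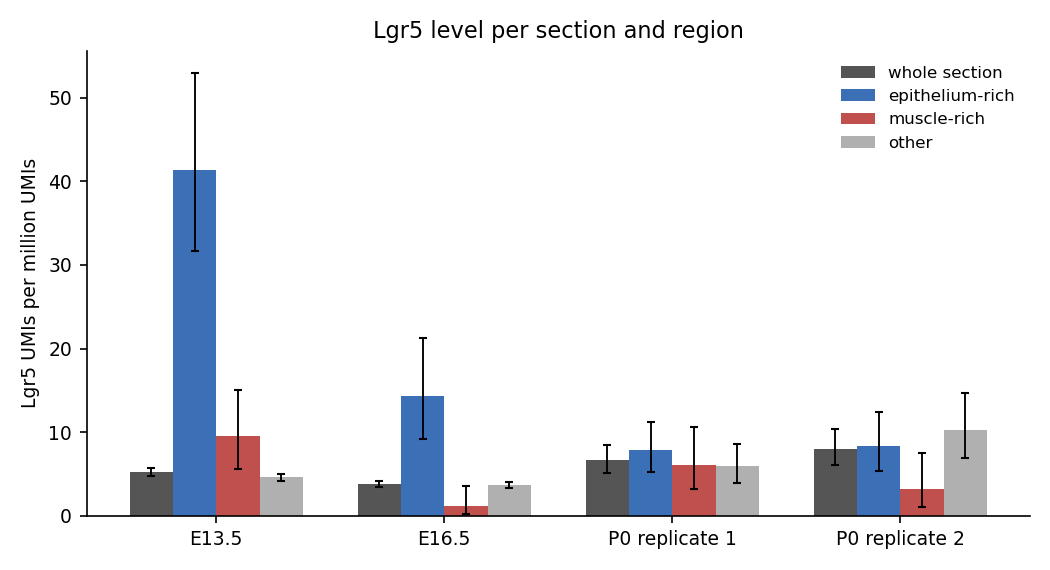
Lgr5 level (CPM, vertical axis from 0) over each whole section (dark grey) and in its epithelium-rich, muscle-rich and other spots; bars are values per section and lines 95% Poisson intervals of counting error. The E13.5 epithelium-rich bar (41.3 CPM) stands above the other bars, while the P0 bars lie between 3.19 and 10.3 CPM.

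**Figure D2:**
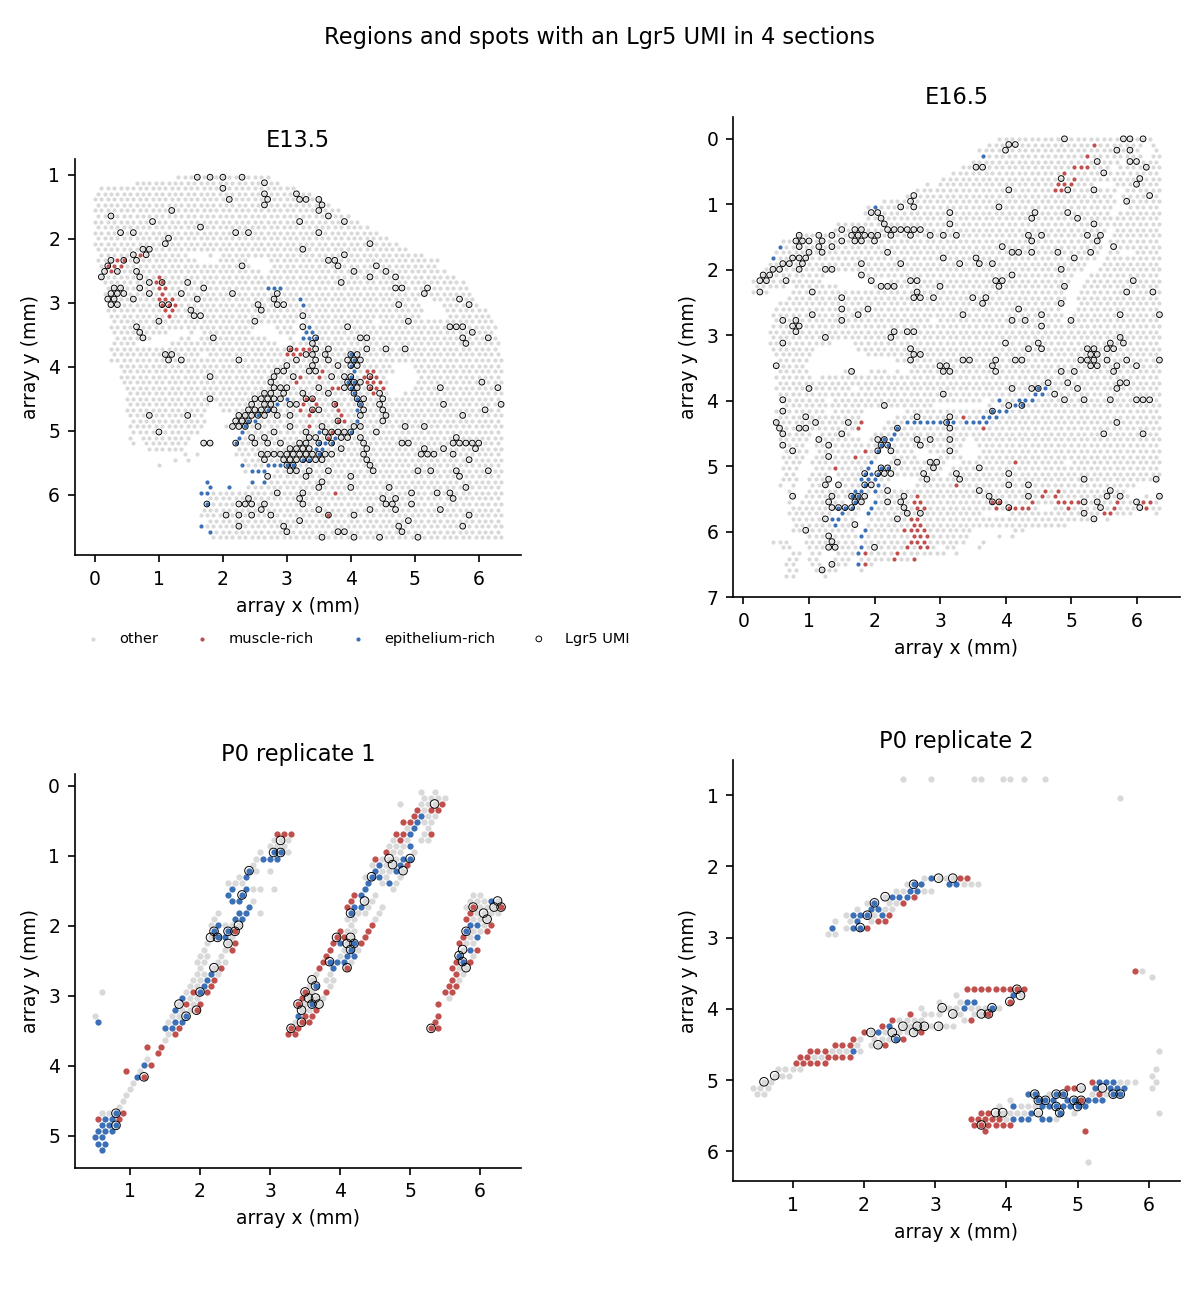
Position of each kept spot (axes in mm) in the 4 sections, coloured blue for epithelium-rich, red for muscle-rich and grey for other spots, with black circles around spots with at least 1 Lgr5 UMI. The embryo panels show 370 (E13.5) and 338 (E16.5) circled spots spread over the section, and the P0 panels 58 and 44 on 3 elongated pieces of tissue each.

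Epithelium-rich and muscle-rich spots of the P0 esophagus were then compared for every gene, with the 2 sections as replicates. Keratins and cornified-envelope genes of the stratified epithelium were higher in epithelium-rich spots, and contractile genes of smooth and striated muscle were higher in muscle-rich spots. The spots were chosen by epithelial and muscle markers in these same counts. Differences in other epithelial and muscle genes, and in their lists, are therefore largely given by the choice, although the markers were left out. Krt13 and Krt4, the keratin pair of the differentiating esophageal layers, reached 17280 ± 601 CPM and 17292 ± 938 CPM (SD, n = 2) in epithelium-rich spots against 1791 ± 62.6 and 1826 ± 170 CPM in muscle-rich spots. Des, the intermediate filament of muscle, had 1397 ± 133 CPM in muscle-rich spots against 85.7 ± 31.3 CPM. Of 12689 genes tested, 3382 were higher in epithelium-rich spots and 3730 lower, and 6977 of these 7112 went the same way in both sections.

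The largest increases towards the epithelium were those of Cstdc5 (ENSMUSG00000071561, chromosome 16, 36359382 to 36367570), a cystatin family member, with a log2 fold change of 4.88 ± 0.30 (SE, adjusted p = 4.07e-11), and Cwh43 (ENSMUSG00000029154, chromosome 5, 73406051 to 73453435), which acts on lipid anchors, with 4.72 ± 0.22 (adjusted p = 7.37e-13). The other 10 genes named by the rule had log2 fold changes from 4.07 (Arg1, arginase) to 4.32 (Ccl6, a chemokine). They included the cornified-envelope proteins Sprr3 (4.23 ± 0.15) and Sprr2a3 (4.13 ± 0.30), the keratin Krt6b (4.31 ± 0.18), the protease Tmprss11b (4.17 ± 0.19), the antimicrobial peptide Defb1 (4.15 ± 0.19), the transcription factor Elf5 (4.14 ± 0.22), the chemokine Ppbp (4.09 ± 0.17) and the membrane protein Mal (4.09 ± 0.15).

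All 21 tested members of the suprabasal epithelium list rose (median log2 fold change 3.47, 21 adjusted over the list alone), among them Krt6a (3.70 ± 0.12), the transglutaminase Tgm3 (3.67 ± 0.13) and the envelope precursor Sprr1a (3.87 ± 0.18). Its camera adjusted p was 1.00e-20, and the adjusted p = 0.230 with an estimated correlation. Of 15 basal epithelium genes 13 rose (median 2.23, camera adjusted p = 2.65e-06), including Trp63, the master regulator of stratified epithelia (2.02 ± 0.14), the hemidesmosomal collagen Col17a1 (2.35 ± 0.14) and the transcription factor Klf5 (2.84 ± 0.12), with an adjusted p = 0.266 with an estimated correlation. Isl1, a transcription factor also active in neurons, fell (−4.36 ± 0.49). All 3 tested mesothelium genes rose (median 3.40, camera adjusted p = 0.000592, and adjusted p = 0.266 with an estimated correlation), but these were Msln, Upk3b and Upk1b, which epithelial surfaces also express. Of 10 stress response genes 7 rose (8 adjusted over the list alone, median 1.07, camera adjusted p = 0.000927, and adjusted p = 0.266 with an estimated correlation), led by the immediate early gene Junb (2.73 ± 0.11).

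Among the genes higher in muscle-rich spots, Pcp4 (ENSMUSG00000090223, chromosome 16, 96467606 to 96525793), a calmodulin regulator, had the largest change (−5.39 ± 0.24, adjusted p = 2.43e-13), followed by the muscarinic receptor Chrm2 (ENSMUSG00000045613, chromosome 6, 36387991 to 36528638) at −5.32 ± 0.27 (adjusted p = 2.40e-12). The other 10 ran from −4.53 (Cox6a2, a muscle cytochrome oxidase subunit) to −5.09 (Fgl2). They held the sarcomere genes Myh7 (−4.97 ± 0.23), Tnnt1 (−4.66 ± 0.23), Myl1 (−4.64 ± 0.18) and Myl4 (−4.54 ± 0.19), Itgb1bp2, which encodes the muscle protein melusin (−4.57 ± 0.21), and genes of enteric nerves and glia: the neuropeptide precursor Cartpt (−5.03 ± 0.36), Uchl1 (−5.0 ± 0.30) and the endothelin receptor Ednrb (−4.78 ± 0.20).

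All 18 smooth muscle genes fell in epithelium-rich relative to muscle-rich spots (18 adjusted over the list alone, median −3.20, camera adjusted p = 1.53e-16), for example Myl9 (−3.42 ± 0.12) and Synpo2 (−4.09 ± 0.17). All 24 striated muscle genes fell as well (24 adjusted over the list alone, median −4.50, camera adjusted p = 6.43e-15), for example Ckm, muscle creatine kinase (−3.83 ± 0.15), Tnnc2 (−4.33 ± 0.15) and the myogenic factor Myog (−4.35 ± 0.17). Both lists had an adjusted p = 0.230 with an estimated correlation. Of 10 muscle progenitor genes 8 fell (median −3.50, camera adjusted p = 0.00589, and adjusted p = 0.266 with an estimated correlation), such as Msc (−4.56 ± 0.33), while the receptor Met rose (0.49 ± 0.17, adjusted p = 0.783 with striated markers alone). Tbx1 had −0.40 ± 0.22 (adjusted p = 0.135), and its log2 fold change turned to 0.66 with smooth muscle markers alone. Striated muscle levels differed between the P0 sections: Tnnc2 had 89.2 CPM over all spots of replicate 1 and 344 CPM in replicate 2.

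Lists of supporting tissue, nerves, immune cells, blood and liver were also lower in epithelium-rich than in muscle-rich spots. Other spots were not part of this contrast, so it does not place these genes in the muscle. All 17 fibroblast and matrix genes fell (median −2.09, camera adjusted p = 4.24e-13), as did 9 of 9 endothelial genes (−2.09, 0.000592), 12 of 13 enteric neuron and glia genes (−3.63, 0.00115), 4 of 4 genes of interstitial cells, the pacemakers of gut muscle (−2.27, 0.00609), 8 of 9 immune genes (−1.76, 8.60e-05), 5 of 5 blood genes (−3.20, 0.000592), 6 of 6 liver genes (−3.20, 0.00496) and 5 of 5 central nervous system genes (−3.99, 0.00609). With an estimated correlation these 8 lists had an adjusted p from 0.230 (endothelium) to 0.347 (enteric). Examples are Col1a1 (−1.91 ± 0.11), the glial factor Sox10 (−4.73 ± 0.49) and the receptor kinase Kit (−2.55 ± 0.19); in the enteric list Erbb3, a neuregulin receptor that epithelia also express, rose (1.80 ± 0.15). All 12 proliferation genes fell by a smaller amount (median −0.67, camera adjusted p = 0.000855, and adjusted p = 0.230 with an estimated correlation), with Mki67 at 50.6 ± 6.23 CPM in epithelium-rich and 94.8 ± 10.3 CPM in muscle-rich spots.

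In the Hedgehog list the ligand Shh rose in epithelium-rich spots (2.29 ± 0.26, 26.4 ± 3.89 against 6.28 ± 2.55 CPM) and 9 of 13 members fell, including the targets Gli1 (−1.37 ± 0.22), Hhip (−2.20 ± 0.21) and Foxf1 (−2.80 ± 0.19), while the receptor Ptch1 had −0.09 ± 0.14 (list median −1.37, camera adjusted p = 0.00341, and adjusted p = 0.266 with an estimated correlation). In the BMP list 12 of 17 fell (median −1.82, camera adjusted p = 0.000592, and adjusted p = 0.230 with an estimated correlation) and Bmp7 rose (0.63 ± 0.21, but −0.07 with striated markers alone). The ligand Bmp4 (−1.93 ± 0.30), the antagonist Grem1 (−4.43 ± 0.35) and the target Id3 (−2.83 ± 0.15) were higher in muscle-rich spots. Wnt ligands and modulators went both ways (5 higher, 9 lower of 16, 10 lower adjusted over the list alone, median −0.99, camera adjusted p = 0.267): Wnt4 (3.09 ± 0.16, 260 ± 24.3 against 37.2 ± 10.5 CPM) and Wnt7b (2.99 ± 0.26) were higher in epithelium-rich spots, and Wnt5a (−2.87 ± 0.21), the R-spondin Rspo3 (−4.45 ± 0.61) and Sfrp1 (−2.10 ± 0.14) were higher in muscle-rich spots.

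The Wnt receptors and feedback list had 5 members higher and 6 lower of 15 (6 higher adjusted over the list alone). Its median was 0.00, its mean −0.24 and its test upward (camera adjusted p = 0.953). Lgr4, the paralog of Lgr5, rose (0.89 ± 0.16), Lgr6 fell (−2.98 ± 0.66), the ubiquitin ligase Rnf43 rose (1.39 ± 0.33) and the feedback genes Axin2 (−1.38 ± 0.31) and Nkd1 (−2.25 ± 0.15) fell. FGF genes (2 higher, 7 lower of 12, median −1.13, camera adjusted p = 0.174) held the epithelial receptors Fgfr2 (1.68 ± 0.13) and Fgfr3 (2.63 ± 0.15) and the muscle-side Fgfr1 (−2.83 ± 0.15). Notch genes (7 higher, 4 lower of 13, median 0.50, mean −0.20, camera adjusted p = 0.152) held Hes1 (2.28 ± 0.12) and Jag2 (1.5 ± 0.17) on the epithelial side and Heyl (−4.07 ± 0.32) on the other. Ciliated and columnar (3 higher, 1 lower of 4, camera adjusted p = 0.621), stomach (3 lower of 5, 0.215) and heart genes (1 higher, 2 lower of 3, 0.179) did not pass as lists. Cartilage and the thymus and thyroid list had too few tested members.

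Of 25 lists tested 18 passed 0.05 with the preset correlation and 0 with an estimated correlation, at 2 residual degrees of freedom. Without the replicate block 17 lists passed, the liver list being lost (adjusted p = 0.227).

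**Figure D3:**
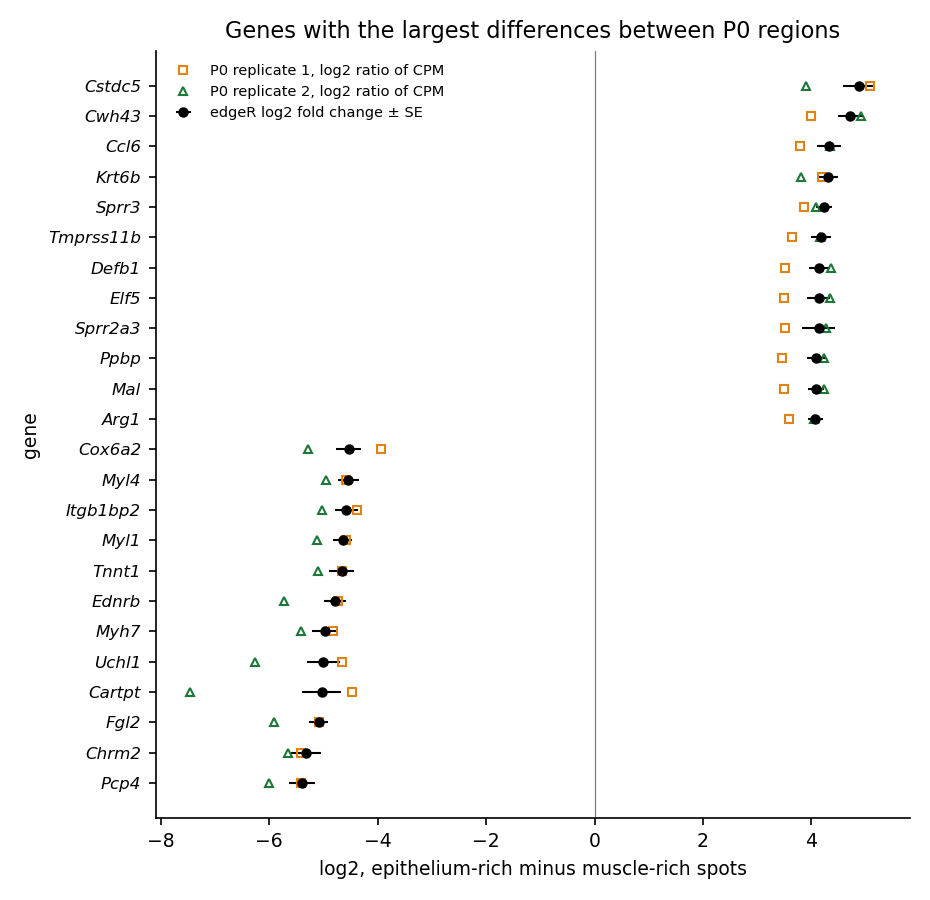
Log2 difference between epithelium-rich and muscle-rich P0 spots (horizontal axis) of the 24 genes named by the rule; black points are edgeR log2 fold changes with lines for the SE, and open squares and triangles are log2 ratios of CPM in replicates 1 and 2. The values run from 4.88 (Cstdc5) to −5.39 (Pcp4), with both sections on the same side of 0 for each gene.

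**Figure D4:**
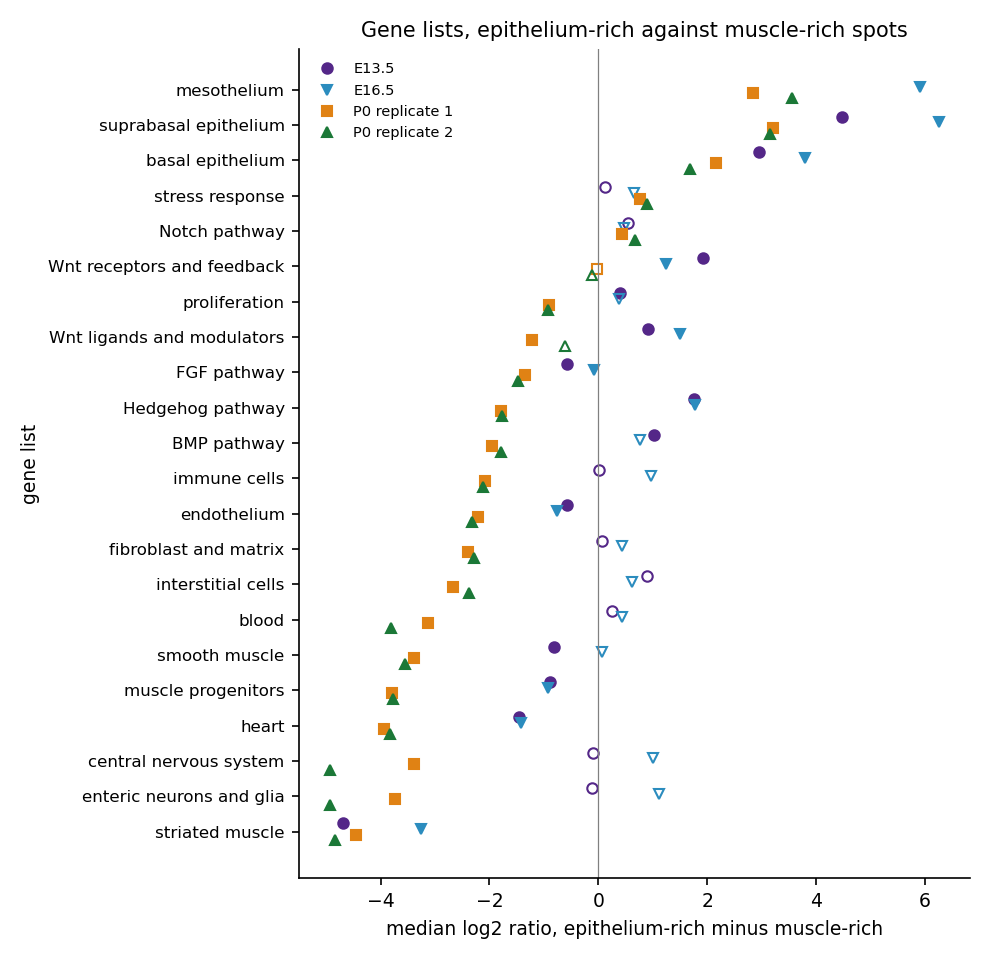
Median log2 ratio of each gene list, epithelium-rich over muscle-rich spots, a symbol per section; filled symbols lie outside the central 95% of random lists, open symbols within. The suprabasal list is to the right of 0 in every section, and the Hedgehog list lies at 1.76 (E13.5) and 1.78 (E16.5) but at −1.78 and −1.77 in the P0 sections.

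P0 spots with a Lgr5 UMI were compared with the other spots of the same section, which asks which genes accompany a captured Lgr5 UMI in the esophagus. Only 8 of the 58 and 12 of the 44 spots held at least 2 Lgr5 UMIs. At so low a level the other spots can hold Lgr5 that was not captured, so the groups are not spots with and without Lgr5. None of the 20 genes named by the rule passed the test; those with positive values were mostly epithelial and small in effect, and those with negative values included contractile genes. Grhl1 and Grhl3, transcription factors of the epithelial barrier, had log2 fold changes of 0.62 ± 0.16 and 0.56 ± 0.18 (SE, 2 sections), the junction protein Cxadr 0.52 ± 0.15 and the ephrin Efnb2 0.51 ± 0.15. Tnnc2 had −1.31 ± 0.28, Ckm −1.27 ± 0.27, Myl1 −1.26 ± 0.35, Fgl2 −1.04 ± 0.18 and Des −0.94 ± 0.27. The other 11 were Ap1m2, Rhov, Lrmp, Mir205hg, Tjp3 and Tmprss11a, from 0.50 to 0.56, and Eno3, Tnni2, Tnxb, Synpo2 and Fabp4, from −1.08 to −0.92; adjusted p ran from 0.562 to 0.648.

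Of 12579 genes edgeR called 1, which fell: Ccl21a, in the copy with identifier ENSMUSG00000094686 (Ccl21a_ENSMUSG00000094686), a chemokine of lymphatic vessels. It had a log2 fold change of −3.49 ± 0.38 (adjusted p = 0.0315), with 2.56 and 1.92 CPM in Lgr5-UMI spots against 19.5 and 35.5 CPM in the others. It lies outside the naming rule and was chosen after its values were seen, and near-identical gene copies share its reads. At an unadjusted p under 0.05 there were 810 genes. DESeq2's Wald test also called 1, while with DESeq2 size factors edgeR called 0.

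With the preset correlation 11 lists passed for these spots. The suprabasal list (median 0.29, camera adjusted p = 5.15e-06) and the basal list (0.28, 3.28e-05) were higher, as was mesothelium (0.30, 0.0498). Striated muscle (−0.97, 6.99e-18, 13 of 22 lower adjusted over the list alone), smooth muscle (−0.71, 1.26e-17, 15 of 17), fibroblast and matrix (−0.50, 1.74e-16, 10 of 17), immune cells (−0.66, 2.37e-09, 6 of 9), endothelium (−0.48, 6.51e-05), stomach (−0.74, 0.000615), liver (−0.52, 0.0243) and blood (−0.57, 0.0453) were lower. With an estimated correlation all 11 had an adjusted p from 0.793 to 0.855. The sections differed: blood had a median of 0.55 in replicate 1 and −2.36 in replicate 2, the liver list 0.77 and −1.48, and the mesothelium list −0.09 and 0.64. The striated list had 0.01 and −1.76, and the suprabasal list −0.09 and 0.62, while the basal list had 0.35 and 0.25. Across genes 51.6% of log2 ratios had the same sign in both sections (Pearson's r 0.07 across genes, which are not independent replicates). Lgr5-UMI spots were deeper, with medians of 30671.5 and 33167 UMIs against 24278 and 24315. With other spots matched on total UMIs 4 of the lower lists were no longer low in replicate 1. There smooth muscle had 0.0423, fibroblast and matrix 0.0629, immune cells 0.12 and endothelium 0.16, while replicate 2 had −0.93, −0.30, −0.63 and −1.15. With region matched too, chosen after the data were seen, replicate 1 had immune cells low again (−0.34), smooth muscle at 0.16 (17 of 17 higher) and striated muscle at 0.31, and replicate 2 had −0.54, −0.52 and −1.18. With each of the 3 large pieces of tissue per section as the replicate, chosen after the data were seen, 255 genes passed (52 higher, 203 lower).

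Spots with a Lgr5 UMI were described in the embryo sections in the same way, where they cover many organs. At E13.5 genes of epithelium and of striated muscle were both higher in Lgr5-UMI spots, and heart genes lower. All 15 basal epithelium genes were higher (median log2 ratio 0.78, percentile 100 of random lists), as were 14 of 17 suprabasal genes (0.80, 100) and 20 of 24 striated muscle genes (1.05, 100), including Myog (1.19). The muscle progenitor list had 0.45, Wnt ligands 0.44, FGF genes 0.44, Wnt receptors 0.30, Hedgehog 0.27 and proliferation 0.31 (12 of 12), each above the central 95% of random lists. Matched on total UMIs and region, chosen after the data were seen, the basal (0.13), suprabasal (0.0467) and Hedgehog lists (0.12) lay within it, and the striated list had 0.50. Heart (−1.42, Nppa −2.44), liver (−0.76) and central nervous system genes (−0.56) lay below it. Smooth muscle genes had −0.04 (percentile 10.7), and the smooth muscle markers that define regions −0.63.

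The largest single increases at E13.5 were those of Dbh (2.61, 71.3 against 11.7 CPM) and Th (2.47), enzymes of catecholamine synthesis, Pitx1, a transcription factor of hindlimb and oral epithelium (2.12), and the granins Chgb (1.82) and Chga (1.13). Few spots carried some of these: 5 spots held 72.1% of the Dbh UMIs and 75.3% of the Chgb UMIs among Lgr5-UMI spots, against 24% for Pitx1 and 18.9% for Myog.

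At E16.5 the ciliated and columnar list was highest in Lgr5-UMI spots (median 1.88, 9 of 10 members), with the ciliary genes Ccdc153 (2.05) and Dynlrb2 (1.93). The airway secretory genes Scgb3a1 (2.38, 307 against 58.9 CPM) and Scgb3a2 (2.16, 1572 against 351 CPM) and the mucin Muc5b (2.28) led the single genes, with 5 spots holding 63.0% of the Scgb3a1 UMIs. Fibroblast and matrix (0.54), immune (0.55), Wnt ligand (0.51), stress response (0.47, 9 of 10), suprabasal (0.42), basal (0.41) and Hedgehog genes (0.40) also lay above the central 95% of random lists. Heart (−0.82), striated muscle (−0.14, percentile 0.05) and proliferation genes (−0.13) lay below it. The lowest single genes were Smgc (−3.11) and Bpifa2 (−2.95), secreted proteins of salivary glands. With the same matching on total UMIs and region the E16.5 suprabasal list turned to −0.53 (4 of 22 higher) and the basal list to −0.0811, stress response (0.19) and Hedgehog genes (0.21) lay within the central 95%, and the ciliated and columnar list had 0.49. With it the epithelial markers fell from 0.78 to 0.036 at E13.5 and from 0.64 to −0.11 at E16.5.

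**Figure D5:**
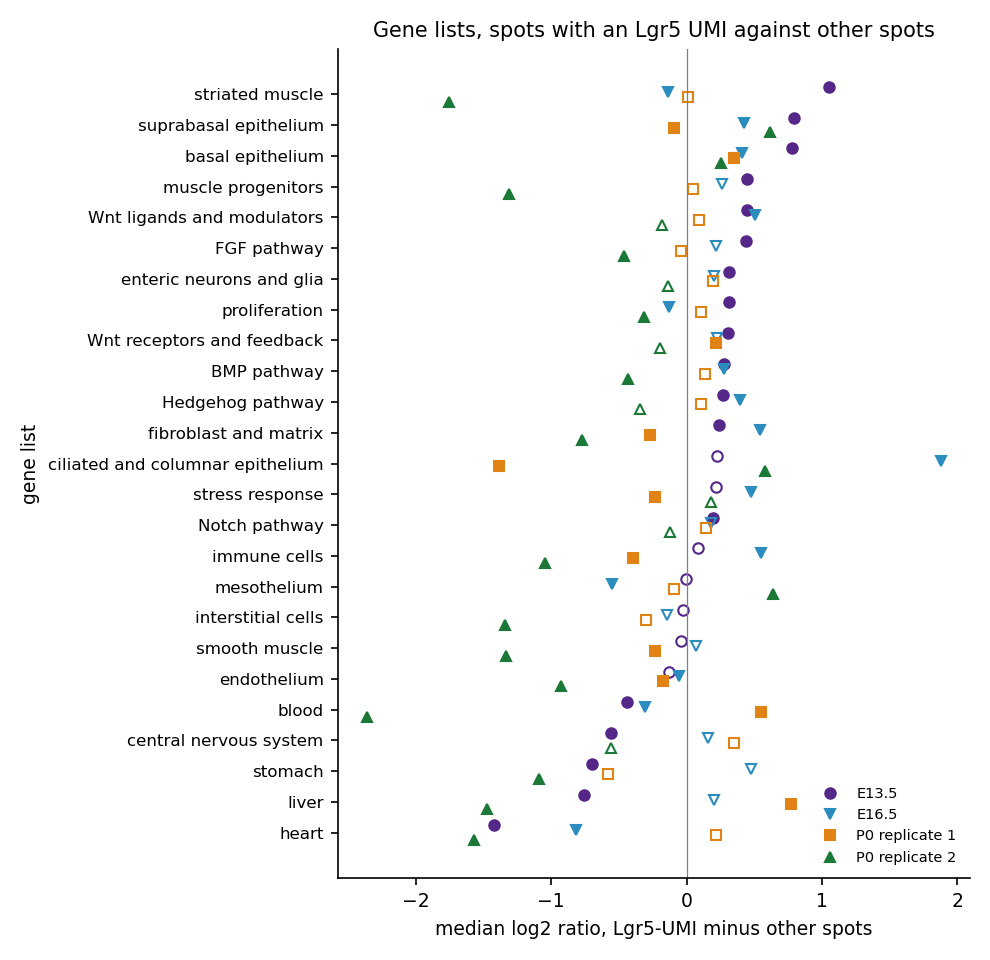
Median log2 ratio of each gene list, spots with at least 1 Lgr5 UMI over other spots, a symbol per section; filled symbols lie outside the central 95% of random lists, open symbols within. The striated muscle list lies at 1.05 at E13.5, −0.14 at E16.5, 0.01 in P0 replicate 1 and −1.76 in P0 replicate 2.

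Stages were compared in spots of upper-digestive-type epithelium, those with at least 2 UMIs of epithelial markers, at least 1 UMI of Sox2, Pax9, Foxe1, Krt4 or Krt13, and 0 UMIs of epidermis and airway markers. Suprabasal genes were higher at each later stage, and striated muscle genes were highest at E16.5. The suprabasal list had a median log2 ratio of 1.32 from E13.5 to E16.5 (8 of 11 higher) and 4.16 from E16.5 to P0 (18 of 18). The basal list had 0.40 and 2.86, or 2.26 with genes at 0 put at 3 counts per sum. Striated muscle genes had 2.60 (23 of 24 higher) and then −2.21 (0 of 24). Hedgehog genes had −1.21 and then 1.13, and Wnt ligands −1.39 and then 1.04. Each of these lay outside the central 95% of random lists. The basal list turned to −0.15 at the earlier step with each spot thinned to 2000 UMIs. Lgr5 had a log2 ratio of −0.97 (−2.94 to 0.54, 29 and 4 UMIs) from E13.5 to E16.5 and 0.92 (−0.61 to 2.90) from E16.5 to P0, so a difference was not detectable in these spots. Thinned to 2000 UMIs, where other spots pass the rule, the ratio from E13.5 to E16.5 was −3.58 (−5.91 to −1.36, 5 and 4 UMIs).

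The rule picked 179, 78, 134 and 85 spots that were shallow, with medians of 25262, 14254.5, 19783.5 and 16806 UMIs, and it drew in other organs: the genes named by the rule included at E16.5 the salivary Smgc (1662 CPM) and Bpifa2 (675 CPM) and pituitary growth hormone Gh (1514 CPM), and at E13.5 the liver gene Afp (385 CPM). At P0 the chloride channel regulator Clca3b (435 and 288 CPM), the transporter Slc6a14 (228 and 211 CPM) and the interferon-related Ifit1bl1 (388 and 347 CPM) had the largest increases.

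A definition chosen after these values were seen took the epithelium-rich spots whose upper digestive markers outnumbered those of epidermis and airway (39 spots at E13.5, 63 at E16.5, 91 and 66 at P0). There Krt13, itself among the markers that selected these spots, had 3.18 CPM at E13.5 (0.656 to 9.29), 5281 CPM at E16.5 and 17705 and 16856 CPM at P0, and Psca, a surface protein of differentiating epithelium, had 0 CPM at E13.5 (upper bound 3.91), 1153 CPM at E16.5 and 11504 and 11987 CPM at P0. Krt5, the basal keratin and also a selecting marker, had 301, 702, 1205 and 1142 CPM and Trp63 85.8, 72.3, 104 and 110.5 CPM. The suprabasal list had 4.15 (18 of 18 higher) and then 1.60 (18 of 20), and the stress response list moved with it (2.27, then 0.59). Other tissues were present here too: at E16.5 the cartilage collagen Col2a1 had 269 CPM, Smgc 62.5, Gh 52.8 and Bpifa2 34.7 CPM, and striated muscle genes had 2.22 and then −3.54.

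Foxj1, the regulator of motile cilia, was highest at E16.5: it had 0 CPM at E13.5 (upper bound 3.91), 272 CPM at E16.5 (245 to 299.9) and 2.16 and 5.56 CPM at P0. The epithelium-rich spots from which this set was taken held airway markers at 210 CPM at E16.5. They held 1.33 CPM at E13.5 and 5.12 and 4.17 CPM at P0. Stage and the kind of epithelium cannot be told apart for this gene. The Hedgehog list had −1.10 (0 of 12 higher) and then −1.09 (2 of 12, within the central 95% of random lists), so its later value turned from the 1.13 of the rule's spots. Shh stood at 38.1 CPM, then 6.95, then 29.1 and 23.6 CPM at P0, and Gli1 at 62.5, 20.1, 12.1 and 9.73 CPM. Wnt ligands had 0.19 and then −0.76 here, both within the central 95% of random lists and opposite in sign to the rule's spots. Wnt receptors had −0.75 at the later step, against 0.82. Proliferation genes had −1.18 (0 of 12 higher) and then −0.81 (1 of 12), with Mki67 at 195, 106, 55.0 and 46.2 CPM. Genes high at E13.5 were the growth-associated Hmga2 (137 against 4.17 CPM at E16.5), Sox11 (266 against 29.2) and the growth factor Mdk (1403 against 231). Lgr5 had a log2 ratio of −1.61 (−2.42 to −0.84) and then −0.93 (−1.67 to −0.14), from 46.6 CPM at E13.5 (33.9 to 62.6, 44 UMIs) and 15.3 CPM at E16.5 (9.58 to 23.1, 22 UMIs). The epithelium of a whole embryo section can be esophagus, tongue, palate, pharynx or forestomach.

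Spots within 2 rings of the rule's spots and not among them (1420, 765, 215 and 142 spots) were compared last. This set does not keep out epithelial spots that failed the rule. At P0 only 14 and 37 kept spots lay in neither set, so its values are not those of tissue beside the epithelium alone. Lgr5 had 7.69 CPM at E13.5, 3.60 at E16.5 and 7.42 and 7.84 CPM at P0, log2 ratios of −1.10 (−1.50 to −0.71) and then 1.08 (0.60 to 1.56). The later ratio was −0.24 (−5.65 to 2.49) when thinned to 2000 UMIs. With the strip below, set against all kept P0 spots, it was −0.04 (−0.97 to 1.05). Suprabasal genes were higher at each step (3.32, 18 of 19, then 4.01, 19 of 19), and basal genes too (1.02, then 2.93, the former turning to −0.11 in the strip below). Striated muscle genes had 2.38 and then −2.35, smooth muscle genes 0.54 and then 0.75 (−0.31 with the strip), Hedgehog genes −0.94 and then 1.11, and enteric genes −2.08 at the earlier step (0.24 with the strip). Endothelial genes had −1.18 at the later step (0 of 10 higher), and 0.02 with thinning to 2000 UMIs. Smgc (1200 CPM) and Gh (667 CPM) led at E16.5 here too. At P0 the female-specific Xist led (45.4 and 41.6 CPM, against 0 at E16.5), so the sex of the tissue differs as well as the stage, followed by Ifit1bl1 (446 and 450.2 CPM) and Clca3b (512 and 457 CPM).

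In a strip of spots high in the visceral smooth muscle actin Actg2, defined after the data were seen, Lgr5 had 2.27 CPM at E13.5 (0.736 to 5.29, 5 UMIs in 61 spots) and 7.43 CPM at E16.5 (3.56 to 13.7, 10 UMIs in 59 spots), a log2 ratio of 1.71 (0.03 to 3.61), opposite to that of the neighbouring spots. Striated muscle genes had a median of 3.60 there (18 of 18 higher), with Ckm at 0.453 CPM and then 418 CPM. The strip at E16.5 also held the airway genes Scgb3a2 (2870 CPM) and Sftpc (485 CPM).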

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

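The tests of depth and of the Actg2 strip for the E13.5 Lgr5 level, of region for the suprabasal genes and of region for the E13.5 striated muscle genes were chosen only after the result was seen. For depth at E13.5 the matching was planned and its limit set after the result was seen. Lists are called here where their median lay outside the central 95% of random lists in every section of a stage and on opposite sides between stages, and none of these differences between stages was tested.

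Between epithelium-rich and muscle-rich spots the Hedgehog list had a median log2 ratio of 1.76 at E13.5 and 1.78 at E16.5, against −1.78 and −1.77 in the P0 sections. The BMP list had 1.02 at E13.5 and −1.96 and −1.80 at P0. The proliferation list had 0.39 at E13.5 and −0.90 and −0.92 at P0. Muscle-rich spots of the embryo sections were chosen among all muscles of the body and those of P0 within the wall of the esophagus. Between Lgr5-UMI and other spots the striated muscle list had 1.05 at E13.5 and −0.14 at E16.5, and the proliferation list 0.31 and −0.13. The fibroblast and matrix list had 0.24 at E13.5 and 0.54 at E16.5, against −0.27 and −0.77 in the P0 sections, and the immune list had 0.55 at E16.5 against −0.39 and −1.05. With other spots matched on total UMIs P0 replicate 1 had 0.0629 for fibroblast and matrix and 0.12 for immune genes, within the central 95% of random lists. With region matched too the fibroblast list stayed within it there (0.0740), while the immune list lay below it in both sections (−0.34 and −0.54). Suprabasal genes in P0 Lgr5-UMI spots were not higher in both sections. Replicates 1 and 2 had −0.21 and 0.38 with other spots matched on total UMIs, and −0.32 and 0.26 when matched on total UMIs and region.

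Lgr5 was higher in epithelium-rich spots at E13.5 (41.3 CPM) than at P0 (7.82 and 8.34 CPM). Thinning cannot decide on sequencing depth, since it lowers Lgr5 and total UMIs alike and leaves a spot's CPM unchanged on average. With each spot thinned to 10000 UMIs the E13.5 level was 42.6 CPM (27.8 to 62.5). The P0 levels were then 12.1 CPM (6.03 to 21.6) and 4.55 CPM (0.937 to 13.3). Less epithelium in the P0 spots is argued against: Epcam plus Cdh1 were at least 2.21 times the E13.5 level. Both are selecting markers, and the cut was wider at P0. A single site is argued against, since the E13.5 level outside the group of adjacent spots with most Lgr5 UMIs was 32.5 CPM (23.2 to 44.2), but a few sites carry the level: 5 of 22 groups (29 spots) held 57 of 62 Lgr5 UMIs, and the other 35 spots, a division made after the counts were seen, held 5.78 CPM (1.88 to 13.48). Other epithelia than the esophagus in the E13.5 section stay open: the Actg2 strip, chosen without epithelial genes, held 2.27 CPM from 5 UMIs, with Epcam at 55.8 CPM against 268 and 299 CPM over the P0 sections. A fall of Lgr5 in the esophageal epithelium with age is a hypothesis found on these same data. It was not tested, since esophageal epithelium was not told apart from other epithelia in the embryo sections. The design also confounds it with the dissection of the P0 tissue. The Actg2 strip went the other way, from 2.27 CPM at E13.5 (5 UMIs) to 7.43 CPM at E16.5 (10 UMIs).

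Striated muscle genes were higher in E13.5 spots with a Lgr5 UMI (median 1.05, 20 of 24 members). Matching other spots on total UMIs left the list at percentile 100 of random lists but decides nothing on depth, since the medians were already alike (29008.5 and 29302 UMIs). Lgr5 UMIs of the 64 muscle-rich spots alone are argued against as the whole cause, since without those spots the list stayed at percentile 100, with a median of 0.70. The removal cannot decide on muscle in the spots that stayed. It took out only 16 spots with a Lgr5 UMI, and 58 spots scored within 10% of the muscle limit. Region matters for the size, since matching on total UMIs and region gave 0.50 for the list and 0.21 for the striated markers, against 0.97. Lgr5 transcription in or beside developing skeletal muscle stays open and untested, as do stage and the tissues in the section, since the spots cover many body parts and no test told muscle cells from their neighbours within a spot.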

How the results depend on the processing

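Thinning to 10000 UMIs, matching on total UMIs and region, leaving out detached spots, the tissue piece as the block, the marker-led epithelium and the Actg2 strip were chosen only after the data were seen; all other alternatives were planned. In groups of at least 3 adjacent spots E16.5 held 0 Lgr5 UMIs, so the Lgr5 ratio has bounds alone: in neighbours at most −0.69 from E13.5 and at least 0.48 to P0, and in rule spots at most 2.14 and at least −3.30. All 24 genes named between P0 regions kept their direction, and where they had a p-value their side of the threshold, in 380 of 380 values. The 24 values without P0 replicate 1 and the 24 without replicate 2 have a direction alone, which the naming rule fixed. In the counts below such values were likewise judged by direction alone. Of the 6794 genes past 0.05 without the replicate block, 6782 were also past it with the block. Of the values of other genes named between regions 785 kept both, 15 lost the threshold, 5 passed it and 3 reversed: Tbx1 with smooth muscle markers alone (0.66), Bmp7 with striated markers alone (−0.0712) and Ptch1 thinned to 2000 UMIs (0.11). In the values of genes named for Lgr5-UMI spots 232 kept direction and side, 46 passed the threshold, 2 lost it (Ccl21a_ENSMUSG00000094686 with DESeq2 size factors and without the replicate block) and 10 reversed. Ccl21a_ENSMUSG00000094686 was also not called, having no value after the filter, when matched on total UMIs with or without region, thinned to 2000 UMIs or with the piece as block.

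The P0 means without either replicate ran from 6.63 to 8.02 CPM and from 16% to 16.7% of spots. With at least 2 Lgr5 UMIs the shares were 2.48% (E13.5), 1.28% (E16.5), 2.20% and 4.55% (P0), by construction lower. Thinned to 10000 UMIs they were 4.62%, 4.68%, 6.84% and 6.48%, and E16.5 held 5.0 CPM. Thinned to 2000 UMIs they were 1.37%, 1.09%, 1.66% and 0.394%, and the levels 7.03 CPM (E13.5), 5.59 CPM (E16.5) and 1.97 CPM (P0 replicate 2, 1 UMI); fewer UMIs per spot give fewer spots with a UMI, and the cause of the changed levels was not tested. With larger shares of spots Lgr5 had 27.2 CPM in epithelium-rich and 4.06 CPM in other spots at E13.5. With smooth muscle markers alone muscle-rich spots held 0.473 CPM at E13.5 and 9.31 CPM at E16.5, and with striated markers alone 7.87 CPM in P0 replicate 2, since other spots were taken.

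Between P0 regions the DESeq2 Wald test called 4718 genes (2438 lower), thinning to 10000 UMIs 4303 (2091 higher, 2212 lower) and thinning to 2000 UMIs 1312 (662 and 650) of 3673 genes left to test, against 7112; the other 11 settings gave 5180 to 7448. Lgr5 between regions passed 0.05 with DESeq2 size factors (1.01), without the filter (1.03), with smooth muscle markers alone (1.46), with at least 2000 UMIs (1.08) and without detached spots (1.07), and not in the other settings, with an adjusted p from 0.0117 to 0.620; without either replicate it ran from 0.33 to 1.28, and the cause was not tested. It had no value when thinned or with the piece as block, where the filter removed it. Lists past 0.05 went from 18 to 0 with an estimated correlation and to 9 with the piece as block and an estimated correlation; their cause was not tested.

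For P0 Lgr5-UMI spots, against 1 gene, 0 passed with DESeq2 size factors, 0 without the replicate block, 0 thinned to 2000 UMIs, 174 without the filter (174 lower), 2 with matching on total UMIs (1 higher), 18 with matching on region too (5 higher, 13 lower), 23 thinned to 10000 UMIs (3 higher, 20 lower), 55 without detached spots (55 lower) and 255 with the piece as block (52 higher, 203 lower); the cause was not tested. Thinned to 2000 UMIs the signs of Grhl1 (−0.15), Ap1m2 (−0.34), Grhl3 (−0.29), Rhov (−7.28), Lrmp (−6.82), Efnb2 (−1.24), Tjp3 (−0.90), Tmprss11a (−7.25) and Eno3 (0.41) turned, and Lrmp also at 10000 UMIs (−0.46).

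The Lgr5 ratio from E13.5 to E16.5 was −3.58 in rule spots and −1.68 in neighbours when thinned to 2000 UMIs, where other spots pass the rule, and 1.71 in the strip. From E16.5 to P0 it was −0.24 in thinned neighbours, −0.93 in the marker-led epithelium and −0.0436 in the strip, which sets the E16.5 strip against all kept P0 spots, epithelium included; without either P0 replicate it ran from 0.89 to 0.98 in rule spots and from 1.04 to 1.12 in neighbours.

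Lists outside the central 95% of random lists that changed sign from E13.5 to E16.5 were, in rule spots, for thinning to 2000 UMIs FGF (−0.70), basal (−0.15), enteric (0.62), cartilage (0.83), central nervous system (0.49) and heart (4.21), for groups of at least 3 adjacent spots BMP (0.0411), FGF (−0.83), fibroblast (−0.0792) and enteric (0.0164), and for the marker-led epithelium Wnt ligands (0.19), FGF (−0.43), enteric (0.51) and heart (1.30). In neighbours they were for thinning enteric (0.27), cartilage (0.0864) and central nervous system (0.62), and for the strip Wnt receptors (0.25), basal (−0.11), enteric (0.24) and central nervous system (0.60).

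From E16.5 to P0 those in rule spots were for the marker-led epithelium Wnt receptors (−0.75), Wnt ligands (−0.76), Hedgehog (−1.09), smooth muscle (−0.99) and fibroblast (−1.88), for thinning FGF (0.27), muscle progenitors (1.17) and fibroblast (−0.23), and for groups of adjacent spots FGF (0.46) and muscle progenitors (0.74). In neighbours they were for thinning FGF (0.11), muscle progenitors (0.48) and endothelium (0.0240), and for the strip smooth muscle (−0.31). Without either P0 replicate FGF ran from −0.31 to 0.21 in rule spots and liver from −0.36 to 2.90 in neighbours. Of the other list values between stages 381 held and 81 moved; the cause was not tested.

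In embryo Lgr5-UMI spots, matching on total UMIs and region gave epithelial markers 0.0364 (E13.5) and −0.11 (E16.5, reversed), smooth muscle markers −0.0127 and striated markers −0.32 at E16.5, by construction balancing the regions, and the suprabasal and basal lists reversed to −0.53 and −0.0811. At E13.5 it gave the striated list 0.50, against 1.05. Matching on total UMIs gave 0.19 and −0.48 for the muscle markers and 0.29 for mesothelium (reversed) at E16.5, where the cause was not tested. Depth limits the Lgr5 values of small regions: the E16.5 muscle-rich spots held 3 Lgr5 UMIs and the rule spots 4.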

Other observations

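Dividing the P0 sections into pieces was chosen only after the data were seen, and the tests on the pieces were set before their values were known.

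The relatives and partners of Lgr5 differed widely in level. Lgr4 was more abundant than Lgr5 in every section, at 34.2, 25, 50.2 and 59.8 CPM (E13.5, E16.5, P0 replicates 1 and 2), and Lgr6 was highest at E16.5, at 3.27, 16.2, 5.17 and 2.58 CPM. The R-spondins, ligands of these receptors, were highest at E13.5: Rspo1 had 7.73, 3.21, 3.8 and 2.45 CPM, Rspo2 6.19, 3.8, 0.975 and 0.408 CPM and Rspo3 13.1, 5.64, 4.39 and 3.13 CPM. Wnt4 was far higher in the esophagus (178 and 175 CPM) than over the embryo sections (9.09 and 14.4 CPM), and the Wnt antagonist Sfrp2 had 194, 70.4, 82.6 and 65.3 CPM. Axin2, a general target of Wnt signalling, stayed between 8.73 and 13.9 CPM. Within the embryo sections Wnt receptors and feedback genes were higher in epithelium-rich than in muscle-rich spots, with a median log2 ratio of 1.92 at E13.5 (17 of 17 members) and 1.23 at E16.5 (13 of 14), and Wnt ligands and modulators had 0.92 (11 of 14) and 1.5 (12 of 15). Random lists had medians of 0.20 and 0.59 for the receptors and 0.21 and 0.64 for the ligands, so part of the E16.5 values is common to all genes.

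Each P0 section held 3 large elongated pieces of tissue (145, 153 and 61 spots; 111, 56 and 77 spots) and 4 or 20 detached spots. Xist, expressed in female cells, had 85.6, 1.40 and 72.1 CPM in the pieces of replicate 1 and 100.3, 2.56 and 0 CPM in those of replicate 2, and Y-linked genes were high where Xist was low (2.21, 106 and 2.14 CPM; 3.46, 121 and 91.7 CPM). Both embryo sections had Xist at 0 CPM. Lgr5 had 6.15, 7.01 and 6.95 CPM in the pieces of replicate 1 and 9.23, 5.13 and 9.14 CPM in those of replicate 2, within overlapping counting intervals. The sections were close over 10633 genes (Pearson's r 0.988 across genes; SD of the log2 difference 0.242), with 84 genes apart by more than 1 log2, among them the liver gene Alb (2.75 higher in replicate 2) and the striated muscle genes Myl1 (2.06), Tnnc2 (1.95) and Acta1 (1.86).

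Striated muscle genes were unevenly spread along the pieces. Between the ends of the long axis (below percentile 33 and above percentile 67) their log2 differences were 4.10, 4.13 and 1.16 in the pieces of replicate 1 and 3.63, 1.97 and 3.51 in those of replicate 2, each signed so that the higher end counts as positive. The smooth muscle genes differed by −0.95, −0.24, 1.09, −1.70, −0.17 and 1.83 between the same ends, and the epithelial markers by −0.05, −0.03, −1.48, 3.07, 0.04 and −1.37, opposite in sign to smooth muscle in the 3 pieces where they differed by more than 1 log2. Myf5, a factor of muscle precursors, had 1, 17, 0, 8, 0 and 17 UMIs at the high ends and 0 at all low ends, and Pax7, a marker of muscle stem cells, had 3, 6, 0, 2, 0 and 7 UMIs against 0 in 5 pieces and 1 in the last. Myf5 belongs to the striated muscle genes that set which end was high, and Pax7 does not. The stomach peptide Tff2 had 182 UMIs at the striated end of piece 2 of replicate 2 and 0 at its other end. Lgr5 had 5, 17, 3, 11, 4 and 6 UMIs at the striated ends and 10, 4, 6, 3, 2 and 10 at the other ends, higher at the striated end in 3 of the 6 pieces, and these are raw counts with deeper spots at the striated end in 4 pieces.

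Opposite gradients along the length of the tissue were a candidate explanation, with striated muscle entering from an end while smooth muscle recedes. Smooth muscle was lower at the striated end in 4 of the 6 pieces, fewer than the 5 set in advance, and an exact two-sided sign test gave p = 0.688. Depth per spot along the piece stays open for the striated difference in 4 of the 6 pieces. With each spot thinned to 10000 UMIs 6 of 6 pieces kept its direction, but thinning leaves ratios of CPM unchanged on average and cannot decide. The striated end had the deeper spots in 4 of the 6 pieces, fewer than the 5 set in advance. In piece 3 of each replicate it had the shallower spots, with medians of 23495.5 against 34365 UMIs and 26449 against 35839 UMIs. The striated genes were still higher there by 1.16 and 3.51 log2, which argues against deeper spots as the cause in these pieces. An uneven amount of muscle wall along the piece stays open, with both muscle lists higher at the same end in 2 of the 6 pieces, where the epithelial markers were lower. Which end of a piece faced the mouth is not given in the sources used here.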
